A study of Mus musculus with 6 samples.

How the data were processed

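Brain tissue of wild-type mice was extracted with the AllPrep kit (3 libraries) or with TRIzol (3 control libraries). Per the labels' protocols, libraries were made by T7 in vitro transcription amplification, in which RNA polymerase copies cDNA back into RNA, and sequenced as paired reads of 150 bases on an Illumina NovaSeq instrument. The RNA table alone was analysed here; the other omics layers named in the series title were not analysed here. Samples were grouped by their titles, and each column was matched to a sample by name.

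The authors deposited raw counts per gene, whole numbers that are not normalized. Per the submitters' processing notes, the tools used were FastQC 0.11.9, cutadapt, STAR 2.7.9a, featureCounts and limma 3.60.6 with build GRCm39; their settings, including strand and the treatment of reads that map to several places, are not given in the sources used here. The table had 22692 rows for 22584 Ensembl IDs; 94 IDs stood on more than 1 row with identical counts, and the 108 extra rows were removed. The table names 13 mitochondrial mRNAs without a prefix, and they were renamed by Ensembl ID. Of counts from 1 to 20, 64.2% to 71.0% were even in each library, as when both reads of a pair are counted, so counts were also halved as an alternative. No library pair of a method agreed within sampling noise (chi-square per degree of freedom at least 13.6), so all 6 were kept as separate replicates.

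Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalization, quasi-likelihood F-test, Benjamini-Hochberg adjusted p below 0.05, two-sided), with no block for the replicate number, since no label says what the number marks. The SE of a log2 fold change is its size divided by the square root of the F statistic. Confidence intervals came from limma 3.58.1 (limma-trend on log2 CPM with a prior count of 2). Of 40 gene lists with 886 entries, 791 genes were matched by symbol and 29 by Ensembl ID, and 66 were not matched; 38 lists with at least 5 tested members went into camera (preset correlation 0.01, adjusted over lists) and fry. The 2 lists too small to test held mitochondrial rRNA and tRNA, with no gene in the table, and short structured RNAs such as Rn7sk, with at most 40 counts in any library. Lists, thresholds, the naming rule and most alternatives were set before the data were examined. An adjustment over 1 list alone (Benjamini-Hochberg within that list, adjusted p below 0.05) was not in the plan and was not corrected over lists. Genes that co-vary can pass it together. Which 21 lists to describe gene by gene was chosen after their values were seen: the 15 that passed and 6 others. The rule named, among genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the methods, the 12 with the largest log2 fold change in each direction, leaving out unnamed gene models; in each list described, the 2 members with the smallest p and the 2 most abundant; and the references Gapdh, Actb, Malat1, Snap25, Mbp, Gfap, Hba-a1, Hbb-bs and mt-Co1, of which Hbb-bs was not matched. Other genes named were in the lists and are named with their values. Results for 4 genes that the rule named are not reported here.

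Detection was compared after thinning each library without replacement to the smallest total. Single values were compared by exact permutation tests, two-sided, over which 3 against 3 libraries cannot give p below 0.1. Transcript length and GC content were those of the longest annotated transcript in GENCODE release vM21, which is on another build, so it was used only for gene names and these properties and no coordinates are given. They were found for 99.3% of tested genes. Trends on both were removed in one alternative by smooth curves per library (mgcv 1.9.3) as edgeR offsets. Random lists for comparison took each member's place from the 50 genes closest in abundance among the 200 closest in length or GC, 10000 times. A first matching rule took the nearest genes in both ranks at once. It was replaced after its values for these data had been seen, because a simulated list that followed a length trend fell at percentile 2.05 (weak trend) or 0.0 (steep trend) among its random lists. The rule used placed it at percentile 39.55 and 32.4.

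Alternatives were DESeq2 1.42.0 and its size factors, library size alone, limma-voom, limma-trend, no filter, a filter of at least 1 CPM in 3 libraries, other thresholds, the replicate number as a block, and each library left out in turn; the alternatives planned for normalized values did not apply to counts. Tested on simulated data with 16137 genes of AllPrep against TRIzol, the edgeR step recovered 30.7% of genes changed 1.5-fold, 73.9% of those changed 2-fold and 97.3% of those changed 4-fold, and 8.82% of its calls were unchanged genes. Totals per library ran from 36395330 to 50937858 counts, and changes of 1.5-fold were the least often recovered. Of unchanged genes, 95.4% had a 95% interval that covered 0. Simulated genes were drawn independently of each other, and the changed ones were picked among genes with more counts. These rates may thus not hold for measured genes, many of which co-vary, or for genes with few counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.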

Results

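Whole-transcriptome RNA sequencing was carried out on brain tissue of wild-type mice after RNA extraction by either of 2 routes. In 3 libraries the RNA came from the AllPrep kit, a column kit that recovers several kinds of molecule from one lysate. In 3 control libraries it came from TRIzol, a phenol and guanidine reagent from which RNA is precipitated with alcohol. The comparison asks how far the transcriptome measured after the kit differs from that measured after conventional extraction. Total counts were 36395330, 38530661 and 44995120 in TRIzol replicates 1 to 3. They were 43979970, 38552252 and 50937858 in AllPrep replicates 1 to 3. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Fold changes are AllPrep relative to TRIzol. Expression values are counts scaled to TMM-normalized library size (CPM), given as mean ± SD over 3 libraries per method.

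Among genes that passed the test, the one that differed most between the methods was Ttr (ENSMUSG00000061808), which encodes transthyretin, the main secreted product of the choroid plexus epithelium. Ttr rose from 13.9 ± 2.54 CPM in TRIzol (SD, n = 3) to 792 ± 307 CPM in AllPrep (SD, n = 3), a 57.0-fold difference (log2 fold change 5.83, SE 0.32, adjusted p = 0.0024 in edgeR's quasi-likelihood test). It was 1 of 7 genes of the fixed choroid plexus list among the 12 largest increases. In the other direction, the abundant RNAs Snhg11 and Meg3 were 1.76-fold and 1.53-fold lower in AllPrep. Across the transcriptome, 621 of 16325 tested genes changed at an adjusted p below 0.05, of which 412 were higher and 209 lower in AllPrep. At least a 2-fold change was seen for 139 genes, 124 of them higher and 15 lower. The share of higher genes was 66.3% and depended on the scaling, since library size alone gave 343 higher and 305 lower genes, or 52.9% higher. It turned to 37.2% higher (149 higher, 252 lower) with transcript length and GC trends removed. In that fit the median log2 fold change of all genes was -0.048, against -0.011 in the main fit. Part of this turn may thus come from a shift of all genes. Without AllPrep replicates 1, 2 and 3 in turn, 13, 27 and 28 genes passed, and without TRIzol replicates 1, 2 and 3, 147, 2 and 205 genes. Of 49 named genes that passed, Ttr alone also passed in each of these 6 fits.

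**Figure D1:**
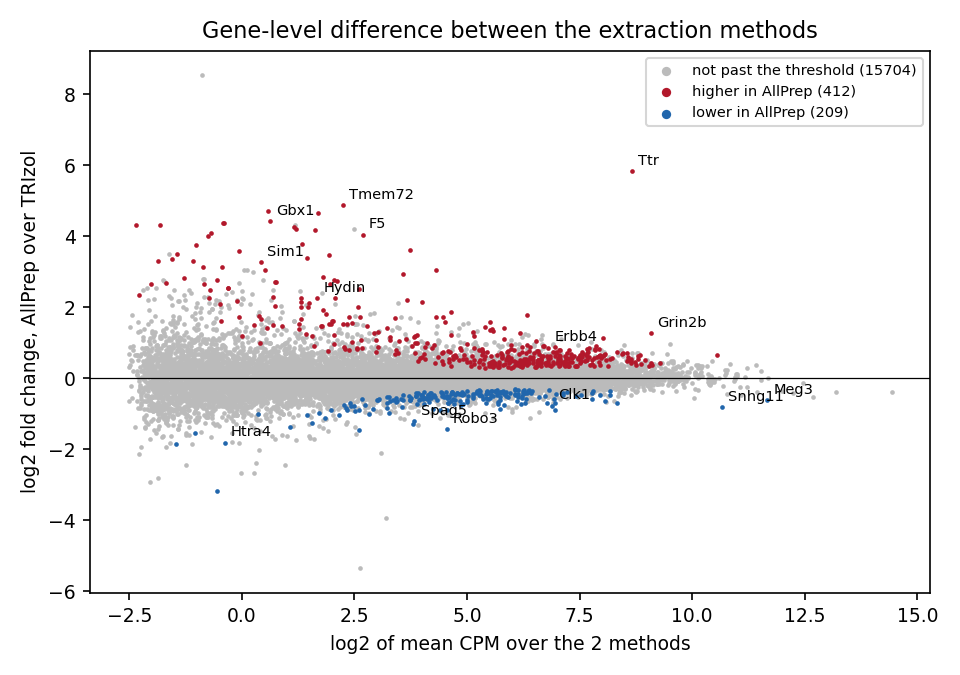
Log2 fold change of each tested gene (vertical axis, AllPrep over TRIzol) against the log2 of its mean CPM over both methods (horizontal axis). Red points are the 412 genes higher and blue points the 209 genes lower in AllPrep at an adjusted p below 0.05 in edgeR; grey points are the other genes, and Ttr lies at 5.83.

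Choroid plexus genes formed the group with the largest shift. Of the 15 listed genes, 13 rose and 2 did not pass the test, with a median log2 fold change of 3.61, and adjusted over the list alone 14 rose. Besides Ttr, Calml4 reached 2.89 ± 1.05 CPM against 0.109 ± 0.0437 CPM (log2 fold change 4.71, adjusted p = 0.012), and Folr1, a folate receptor, 4.24 ± 1.53 against 0.225 ± 0.162 CPM. Tmem72, Slc4a5, a bicarbonate transporter, Kcne2, a potassium channel subunit, and F5, coagulation factor V, had log2 fold changes of 4.87, 4.66, 4.22 and 4.05. The members that did not pass were Enpp2, which other brain cells also express, with 548 ± 96.4 CPM against 334 ± 59.8 CPM (adjusted p = 0.055), and Otx2, named after its values were seen, with a log2 fold change of -0.01. In limma's camera test the list was shifted upward (adjusted p = 1.03e-14), but not with an estimated correlation (adjusted p = 0.32). The other genes among the 12 with the largest increases were not in the list: Gbx1, a homeobox transcription factor (4.44), Prr32 (4.38), Mfrp (4.18), Spata18 (4.09) and Krt8, a keratin of simple epithelia (4.01). Each of the 12 was higher in 3 of 3 AllPrep libraries than in any TRIzol library, as the naming rule required. Their adjusted p-values in edgeR ran up to 0.046, under the rule's limit of 0.05.

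Some ependymal and hypothalamic markers were also higher in AllPrep. Among 13 genes of ependymal and ciliated cells, which line the ventricles, 5 rose and 8 did not pass (median log2 fold change 1.72), and 11 rose when adjusted over the list alone. TRIzol replicate 1 stood apart, with a mean log2 deviation from each gene's mean of 0.05 against -1.35 and -1.61 in TRIzol replicates 2 and 3, and without it the median was 2.55. The ciliary genes Hydin and Dnah11 had log2 fold changes of 2.25 (SE 0.32) and 2.73 (SE 0.39), and Rsph1 went from 2.02 ± 0.693 to 5.84 ± 0.848 CPM. Foxj1, the regulator of motile cilia, had 10.4 ± 1.20 against 6.53 ± 1.80 CPM and did not pass (adjusted p = 0.099). Of 15 hypothalamic genes, 4 rose and 11 did not pass (median 2.05), and 11 rose when adjusted over the list alone. Sim1, a hypothalamic transcription factor, reached 2.44 ± 0.593 against 0.247 ± 0.0996 CPM (adjusted p = 0.016) and Hdc, which makes histamine, 3.75 ± 0.608 against 1.19 ± 0.263 CPM (adjusted p = 0.025). Baiap3 had 110 ± 26.1 against 46.0 ± 21.7 CPM (adjusted p = 0.066), and Cartpt, at 11.7 ± 3.07 and 13.2 ± 16.7 CPM, showed no difference beyond its spread. Camera gave adjusted p = 8.37e-08 for the ependymal list and 5.15e-07 for the hypothalamic list, and with an estimated correlation these were adjusted p = 0.50 and adjusted p = 0.32.

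**Figure D2:**
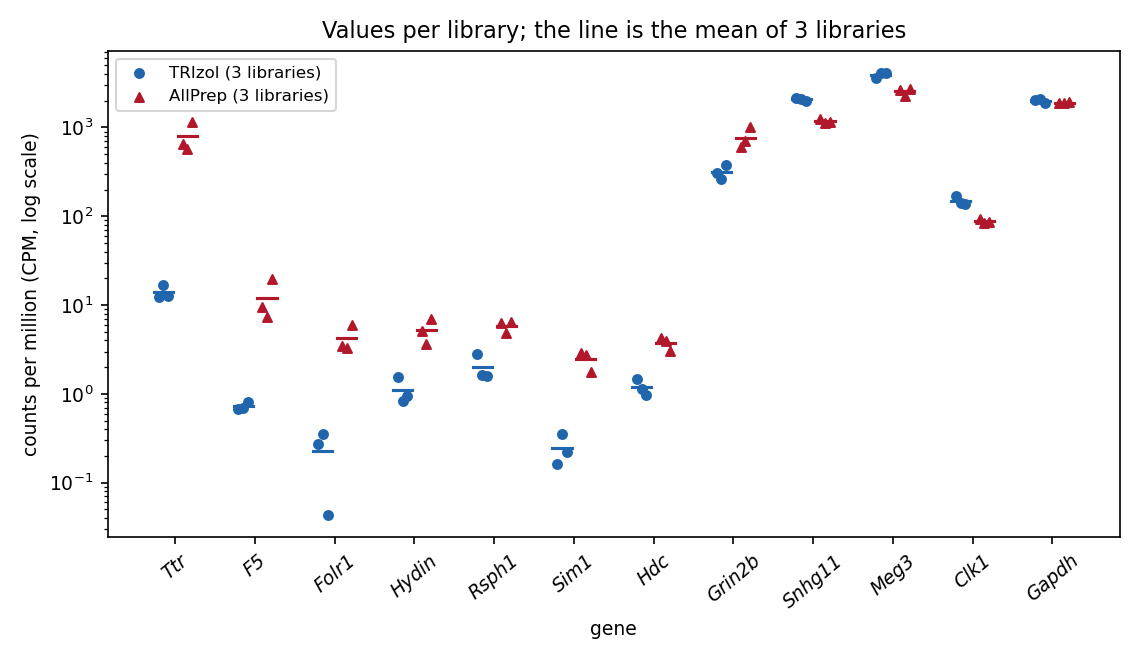
CPM on a log axis for 12 genes in each library, with TRIzol as blue circles, AllPrep as red triangles and a line at the mean of 3 libraries. Ttr lies between 12.3 and 16.8 CPM in TRIzol and between 575 and 1143 CPM in AllPrep, whereas Gapdh overlaps between the methods.

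Some nuclear RNAs and splicing regulators were lower in AllPrep, while most of their lists' genes did not pass. Of 10 tested genes in the list of nuclear-retained long non-coding RNAs, 3 with positive values, 4 fell and 6 did not pass (median log2 fold change -0.39); adjusted over the list alone, 6 fell. Snhg11 (ENSMUSG00000044349) went from 2069 ± 72.7 to 1175 ± 59.1 CPM (log2 fold change -0.82, SE 0.08, adjusted p = 0.012), and Meg3, an imprinted RNA, from 3928 ± 298 to 2565 ± 243 CPM (adjusted p = 0.033). Mirg, from the same imprinted locus, went from 30.6 ± 1.03 to 16.4 ± 2.34 CPM (adjusted p = 0.020). Malat1, an abundant nuclear RNA, had 313 ± 62.6 in AllPrep and 300 ± 61.9 CPM in TRIzol (adjusted p = 0.85). In the list of spliceosome and RNA-binding genes, 6 of 34 fell, 1 rose and 27 did not pass (median -0.22, 7 positive values), and 14 fell and 1 rose when adjusted over the list alone. Clk1 and Clk4, kinases of splicing factors, went from 149 ± 15.6 to 87.5 ± 5.66 CPM and from 91.3 ± 11.1 to 55.0 ± 1.75 CPM (log2 fold changes -0.77 and -0.73). The abundant Ddx5 and Hnrnpu had log2 fold changes of -0.06 and -0.17 that did not pass. Camera placed both lists lower (adjusted p = 0.0046 and 5.36e-06), and with an estimated correlation both had adjusted p = 0.32. Of 914 tested long non-coding RNAs 15 fell and 8 rose, and of 15064 protein-coding genes 191 fell and 402 rose. Snhg11 is annotated as protein-coding in the reference.

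The 12 largest decreases were smaller than the increases. Htra4, a secreted serine protease, fell by 1.81 (log2), from 1.20 ± 0.308 to 0.339 ± 0.0207 CPM, and Robo3, an axon guidance receptor, by 1.43, from 34.2 ± 6.27 to 12.7 ± 4.71 CPM. Spag5, a mitotic spindle protein, went from 19.8 ± 1.47 to 8.61 ± 0.917 CPM (adjusted p = 0.012). Others were Tincr, Cyp11a1, the cholesterol side-chain cleavage enzyme, Chn1os3, Serinc2, Trpv6, a calcium channel, Tmem202, Tnfrsf25 and Ovgp1, with log2 fold changes from -1.36 to -0.96 and adjusted p-values up to 0.045. All 12 were lower in 3 of 3 AllPrep libraries than in any TRIzol library, as the naming rule required. By their names, Chn1os3 and Dlx6os1 lie on the opposite strand of other genes, and since it is not known here whether strand was used in counting, their reads cannot be told from those of their partners.

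Housekeeping lists for proteins and energy had slightly negative medians, with 3 of 184 genes past the threshold. Of 79 cytosolic ribosomal protein genes, 78 had negative values and 1 fell (median log2 fold change -0.33). Adjusted over the list alone, a looser criterion with no correction over lists, 47 fell. Rpl36a went from 70.8 ± 9.70 to 49.5 ± 2.33 CPM (adjusted p = 0.045), while Rpl35, Rpl3 and Rpl4 had log2 fold changes of -0.67, -0.24 and -0.31 that did not pass. All 74 nuclear-encoded oxidative phosphorylation genes had negative values (median -0.31). Uqcrh fell from 83.4 ± 6.42 to 57.5 ± 4.20 CPM and Atp5pf from 114 ± 11.9 to 79.0 ± 4.60 CPM, and adjusted over the list alone 43 fell. The abundant Atp5f1a and Sdha had -0.03 and -0.09. For the proteasome, no gene of 31 passed over all genes and 5 fell when adjusted over the list alone (median -0.18, with -0.29 for Psma3, -0.29 for Psmd12, -0.15 for Psmd2 and -0.42 for Psmc5). Camera gave adjusted p = 1.03e-14, 1.03e-14 and 2.39e-05 for ribosomal proteins, oxidative phosphorylation and proteasome, and with an estimated correlation adjusted p = 0.67, adjusted p = 0.50 and adjusted p = 0.67. Many ribosomal protein genes have processed pseudogenes of near-identical sequence, so their counts are uncertain where reads could be split. Ribosomal protein mRNA made up 0.872% ± 0.0194 of counts in AllPrep and 1.11% ± 0.138 in TRIzol, and mitochondrially encoded mRNA 4.59% ± 0.444 and 6.08% ± 0.779. Each share was lower in 3 of 3 AllPrep libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). None of the 13 mitochondrial mRNAs passed over all genes or adjusted over the list alone. For example, mt-Co1 had 19292 ± 1914 and 25163 ± 2635 CPM (adjusted p = 0.12), mt-Nd1 5357 ± 643 and 7734 ± 1573 CPM and mt-Cytb 8141 ± 679 and 10675 ± 1696 CPM. In camera the mitochondrial list did not pass (median -0.24, adjusted p = 0.13, or 0.82 with an estimated correlation), but it did without TRIzol replicate 2 (adjusted p = 0.0045). The median was -0.10 without TRIzol replicate 1 and -0.13 without AllPrep replicate 3 (adjusted p = 0.33 and 0.43 in camera). In these list values mt-Co2, mt-Co3, mt-Atp6, mt-Nd3, mt-Nd4l and mt-Atp8 weigh as much as abundant members. None of them had more than 1247 counts in a library. With length and GC trends removed the median of the mitochondrial list was -0.0001, with 6 positive and 7 negative values.

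Some long neuronal and synaptic genes were higher in AllPrep, but most members of their lists did not pass. The pan-neuronal and glutamatergic lists had medians of -0.04 and -0.18, each with 10 of 15 values negative, and did not pass in camera (adjusted p = 0.47 and 0.66). In the list of very long brain genes, 5 of 33 rose and 28 did not pass (median log2 fold change 0.29), and 8 rose when adjusted over the list alone. Erbb4, a neuregulin receptor, went from 79.2 ± 4.41 to 144 ± 18.9 CPM (log2 fold change 0.87, adjusted p = 0.020), Csmd3 from 43.4 ± 4.37 to 66.0 ± 8.19 CPM and Dlg2, a postsynaptic scaffold, from 376 ± 14.7 to 490 ± 19.8 CPM. All 24 postsynaptic density genes had positive values (median 0.23). The median was 0.15 without AllPrep replicate 3 and 0.34 without AllPrep replicate 1. Of the 24 genes 2 rose, and 5 did so when adjusted over the list alone. The 2 that passed over all genes were the glutamate receptor genes Grin2b, from 317 ± 57.5 to 770 ± 215 CPM (2.43-fold, adjusted p = 0.032), and Grm5, from 206 ± 14.1 to 323 ± 44.8 CPM, while Camk2a and Camk2b had log2 fold changes of 0.28 and 0.14 that did not pass. Of 23 synaptic vesicle genes 1 rose (median 0.17), Pclo, from 285 ± 24.6 to 466 ± 68.9 CPM, and 3 did when adjusted over the list alone; Atp6v0a1, Snap25 and Syt1 had 0.30, -0.39 and -0.03 and did not pass. Among 15 GABAergic genes 1 rose (median 0.44), Dlx6os1, from 11.7 ± 2.40 to 23.1 ± 2.91 CPM, and when adjusted over the list alone 3 rose and 1 fell. Pvalb, a marker of fast-spiking interneurons, had 28.5 ± 11.2 against 56.0 ± 3.24 CPM (adjusted p = 0.084), and Gad1 had a log2 fold change of 0.17 that did not pass. Camera gave adjusted p = 2.39e-05 for very long genes, 8.45e-05 for the postsynaptic density, 0.035 for GABAergic and 0.039 for synaptic vesicle genes. With an estimated correlation these became adjusted p = 0.32, adjusted p = 0.67, adjusted p = 0.50 and adjusted p = 0.68. The GABAergic call in camera was lost without AllPrep replicates 1 or 2 or TRIzol replicate 3 (adjusted p = 0.0504, 0.071 and 0.069). The synaptic vesicle call was lost without AllPrep replicates 2 or 3 or TRIzol replicate 3 (adjusted p = 0.10, 0.12 and 0.10). Without AllPrep replicate 3 the synaptic vesicle median was 0.10.

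Striatal, matrix and myelin lists passed camera at the preset correlation although at most 1 of their members passed. All 14 striatal genes had positive values (median log2 fold change 0.93) and none passed over all genes or when adjusted over the list alone. Pde10a had 290 ± 145 against 143 ± 73.8 CPM, Penk, encoding proenkephalin, 185 ± 77.4 against 85.4 ± 65.7 CPM, and Rarb 7.86 ± 2.64 against 4.54 ± 1.29 CPM. All 15 oligodendrocyte and myelin genes had negative values (median -0.44) and none passed over all genes or when adjusted over the list alone. Values were 1493 ± 415 against 2038 ± 204 CPM for Mbp, with log2 fold changes of -0.50 for Mog and -0.55 for Ermn. Without AllPrep replicate 3 the myelin median was -0.24 (adjusted p = 0.0075 in camera). In that library the list's mean log2 deviation from each gene's mean was -0.71, against -0.03 and 0.09 in AllPrep replicates 1 and 2. For 26 extracellular matrix genes the median was 0.27 and Col5a1 fell from 27.6 ± 2.80 to 14.7 ± 3.07 CPM. When adjusted over the list alone Col18a1 (log2 fold change 0.81) rose and Col5a1 fell. Sparc and Bcan, the most abundant of them, had log2 fold changes of 0.09 and -0.09. Camera gave adjusted p = 0.0093 for striatum, 0.0016 for myelin and 0.020 for matrix genes, and with an estimated correlation each had adjusted p = 0.82. The striatal call was lost without AllPrep replicates 1 or 2 or TRIzol replicate 3 (adjusted p = 0.058, 0.071 and 0.16). The striatal median ranged from 0.55 without TRIzol replicate 3 to 1.53 without TRIzol replicate 1, and the list's mean log2 deviation was 0.52 in TRIzol replicate 1 and -0.50 in AllPrep replicate 3. The matrix call was lost without AllPrep replicates 1 or 3 or TRIzol replicate 1 (adjusted p = 0.058, 0.12 and 0.18), and without the last its median was 0.13. In that library the mean deviation was -0.43, against 0.06 and -0.02 in TRIzol replicates 2 and 3. The list of meningeal fibroblast genes had -1.21, 0.24 and 0.16 in the same order.

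**Figure D3:**
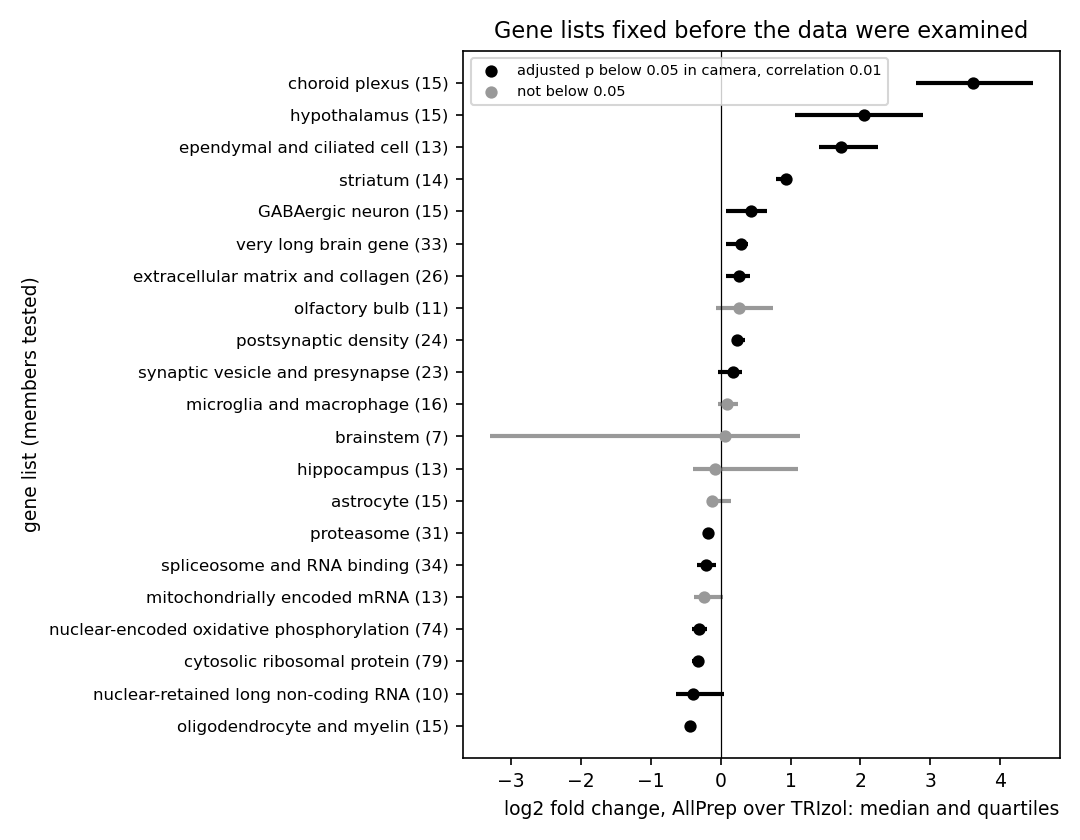
Median (point) and quartiles (bar) of the members' log2 fold changes, AllPrep over TRIzol, for 21 gene lists with the number of members tested. Black marks the 15 lists with an adjusted p below 0.05 in camera at a preset correlation of 0.01, from choroid plexus at 3.61 to oligodendrocyte and myelin at -0.44; none of the 15 passed with an estimated correlation.

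In all, 15 of 38 tested lists passed camera at the preset correlation, 9 upward and 6 downward, and 0 passed with an estimated correlation. A one-way fry test, which asks whether a list's genes move on balance in one direction, passed 5 lists: choroid plexus, hypothalamus, spliceosome, nuclear non-coding RNA and very long genes. Other splits of the 6 libraries into 3 and 3 gave 8 to 16 lists at the preset correlation. Of the 23 lists that did not pass, 17 are not described gene by gene, a choice made after their values were seen. Their median log2 fold changes ranged from -0.45 to 0.36, with adjusted p of at least 0.074 in camera, and 3 of them passed in at least 1 alternative.

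The change varied with transcript length. Of 3245 genes with the shortest transcripts, up to 1900 bases, 26 rose and 41 fell. Of 3244 genes with the longest, from 5196 bases, 256 rose and 22 fell. Across 16219 genes the log2 fold change correlated with transcript length at a Spearman rho of 0.31, a value across genes that are not independent replicates, against 0.013 for GC content. The slope of log2 CPM per doubling of length, relative to each gene's mean over all libraries, was -0.085, -0.049 and -0.014 in TRIzol and 0.051, 0.039 and 0.058 in AllPrep. Because that mean was subtracted, the slopes compare libraries and do not give the trend with length in a single library. With length and GC trends removed as offsets, an alternative added after the data were examined, 401 genes passed, 149 higher and 252 lower. The median log2 fold change of all genes was then -0.048, against -0.011 in the main fit, which also enters the values below. In that fit 9 named genes no longer passed (adjusted p from 0.051 to 0.27). The log2 fold change shrank for 5 of them: Csmd3 from 0.60 (SE 0.11) to 0.23 (SE 0.10), Dlg2 from 0.38 (SE 0.07) to 0.16 (SE 0.08), Pclo from 0.71 (SE 0.12) to 0.22 (SE 0.10), Grm5 from 0.65 (SE 0.11) to 0.44 (SE 0.11) and Grin2b from 1.28 (SE 0.21) to 0.78 (SE 0.16). For the other 4 it moved by less than its SE: Slc1a3 from 0.42 (SE 0.08) to 0.36 (SE 0.08), Rpl36a from -0.52 (SE 0.11) to -0.42 (SE 0.09), Gbx1 from 4.44 (SE 0.92) to 4.37 (SE 0.91) and Tmem202 from -1.01 (SE 0.21) to -0.93 (SE 0.21). Their adjusted p had been 0.037 to 0.046 and became 0.051 to 0.063. Among the 15 lists, the median went from 0.23 to 0.06 for the postsynaptic density (17 positive and 7 negative values, 0 genes higher) and from 0.27 to 0.06 for matrix genes (14 positive, 12 negative). It went from 0.29 to 0.12 for very long genes, with 1 gene higher, and from 0.17 to 0.10 for synaptic vesicle genes, with 0 higher. Medians were 3.56 for choroid plexus, 1.60 for ependymal, 2.03 for hypothalamic, 0.88 for striatal and 0.41 for GABAergic genes. They were -0.67 for nuclear RNAs, -0.22 for splicing, -0.27 for ribosomal proteins, -0.24 for oxidative phosphorylation, -0.14 for the proteasome and -0.45 for myelin. Camera was not repeated in that fit.

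**Figure D4:**
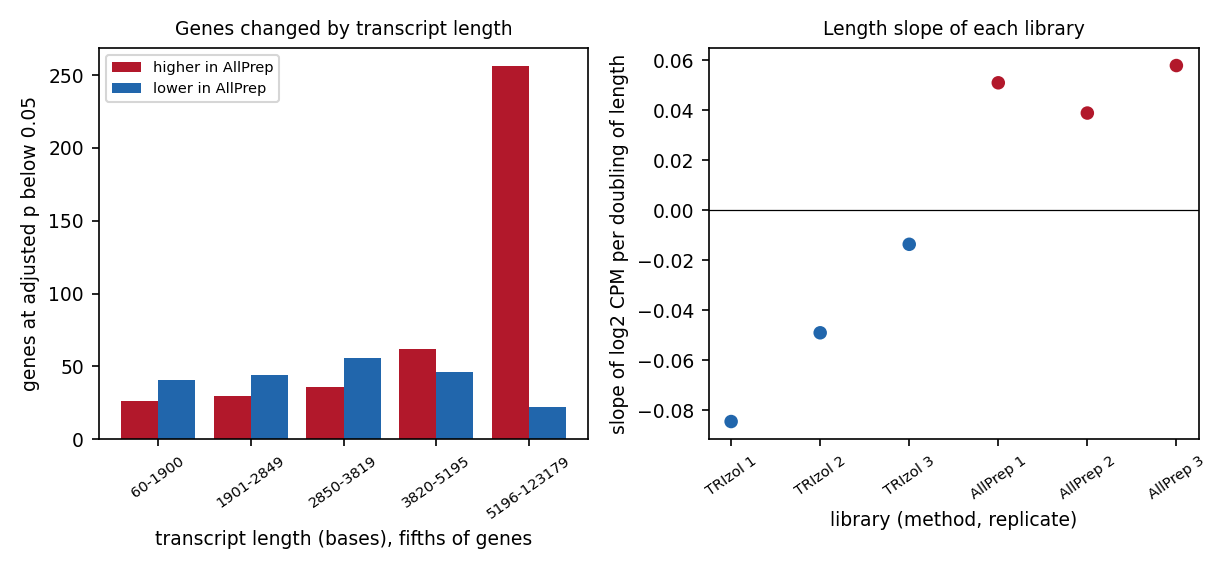
Left, number of genes higher (red) or lower (blue) in AllPrep at an adjusted p below 0.05 in edgeR in 5 equal groups by transcript length in bases, with 256 higher and 22 lower in the longest group. Right, slope of log2 CPM, relative to each gene's mean over all libraries, per doubling of transcript length in each library. It ran from -0.085 to -0.014 in TRIzol (blue) and from 0.039 to 0.058 in AllPrep (red).

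Most genes nevertheless lay within 2-fold between the methods. The 95% confidence interval of the log2 fold change lay within 2-fold for 13033 genes, or 79.8% of those tested, and within 1.5-fold for 9209; for 19.6% it was too wide to decide, and 91 genes lay wholly beyond 2-fold. Other splits of the 6 libraries into 3 and 3, which mix the methods, gave 13111 to 13300 genes with an interval within 2-fold. The 3 AllPrep values lay all on one side of the 3 TRIzol values for 5399 genes (33.1%, against 10% by chance). Gapdh had 1900 ± 15.4 and 2003 ± 106 CPM, Actb 810 ± 36.8 and 736 ± 85.2 CPM and Gfap, the astrocyte filament, 198 ± 36.2 and 166 ± 43.0 CPM in AllPrep and TRIzol, none of which passed. Pearson's r of log2 CPM averaged 0.989 within AllPrep, 0.983 within TRIzol and 0.978 between the methods, and the mean of all within-method pairs exceeded that between methods by 0.0080 (exact permutation over 10 splits, p = 0.1, the smallest possible). The first principal component held 41.6% of the variance and had the 3 TRIzol libraries on one side and the 3 AllPrep libraries on the other.

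Measured spread between replicates was smaller in AllPrep, but whether by more than chance could not be decided. The biological coefficient of variation, the relative spread between libraries beyond counting error, was 0.135 in AllPrep and 0.186 in TRIzol. The difference was 0.0512, and the highest among other splits of the 6 libraries into 3 and 3 was 0.0786. Those splits mix the methods within a group, so the difference between methods enters their spread and they cannot decide it. Without AllPrep replicate 3 the coefficient was 0.0916 in AllPrep. The per-gene SD of log2 CPM had a median of 0.128 in AllPrep and 0.160 in TRIzol and was higher in AllPrep for 6265 genes, or 38.4%; these per-gene values were not tested. At an equal total of 36395330 counts, 19772 ± 162 genes were detected in AllPrep and 19502 ± 101 in TRIzol (exact permutation test, two-sided, p = 0.2). Single counts were thinned. If both reads of a pair were counted, deeper libraries would thus keep more genes than at a truly equal depth. Transcripts of 3 haemoglobin genes, a sign of residual blood, took 0.0010% ± 0.00025 of counts in AllPrep and 0.0013% ± 0.00047 in TRIzol (exact permutation test, two-sided, p = 0.3). Hba-a1 had 8.56 ± 2.25 and 10.7 ± 3.81 CPM. Hbb-bs was not matched, so the share leaves out that gene and may understate residual blood. The 10 and 100 most abundant genes took 5.77% ± 0.461 and 17.5% ± 0.397 of counts in AllPrep against 7.39% ± 0.797 and 19.1% ± 0.730 in TRIzol (exact permutation test, two-sided, p = 0.1 for both).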

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

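The halved counts and the length and GC offsets were chosen only after the data were examined, and the other alternatives were planned. Of the 591 to 621 called genes tested again, 552 to 615 were also called with median-ratio size factors, library size alone, limma-voom, limma-trend, no filter, a strict filter or halved counts. The 49 named genes past the threshold kept their direction in each alternative in which they were tested. limma-voom ended the calls of Gbx1, Trpv6 and Trh, and halved counts that of Gbx1. DESeq2 called 2001 genes, 1248 higher, 753 lower and 314 at least 2-fold. At an adjusted p below 0.1 edgeR called 2021 (1171, 850 and 294), and below 0.01 it called 1 (1 higher, 0 lower, 1 at least 2-fold), against 4212 at an unadjusted p below 0.05. The length and GC offset gave 401 calls, 149 of them higher. With 1 library left out, calls ranged from 2 to 205, higher genes from 2 to 137, lower genes from 0 to 68 and genes changed at least 2-fold from 2 to 68. Fewer libraries by themselves lower such counts; the cause of the other differences was not tested.

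With the replicate number as a block, 236 genes passed (195 higher, 41 lower), 189 of them shared with the fit without it, and the 15 lists kept their calls. The numbers are not known to pair libraries, and deviations of same-numbered libraries from their method's mean correlated at -0.048, 0.0063 and 0.16.

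Camera with an estimated correlation passed 0 lists, with 0.32 the smallest adjusted p, and fry passed 5. The difference in the coefficient of variation, AllPrep minus TRIzol, ranged from -0.0958 without AllPrep replicate 3 to -0.0291 with 1 library left out. Of the 17 lists not described gene by gene, 6 had a median that changed sign in at least 1 of 9 alternatives, mostly medians near 0.

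None of the following genes and lists passed, and their log2 fold changes changed sign. Cartpt had 0.79 in limma-voom, 0.73 in limma-trend and 0.66 with the block. With 1 library left out the ranges were -0.68 to 1.73 for Cartpt, -0.13 to 0.33 for Sparc, -0.066 to 0.014 for Syt1 and -0.58 to 0.077 for Slc17a6. They were -5.93 to 1.59 for Slc6a4 and -4.49 to 0.26 for Tph2, both highest without TRIzol replicate 2. Malat1 had -0.10 with the length and GC offset and -0.10 to 0.24 with 1 library left out. The hippocampal median was 0.35 with the block and -0.40 to 1.29 with 1 library left out, where the list passed without TRIzol replicate 3 (adjusted p = 0.00043). The brainstem median ranged from -0.66 to 1.20.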

Other observations

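The tests on transcript length, GC content, region lists, recovery by the method, nuclear copies and other splits of the libraries were chosen only after the results they bear on were seen. Markers of brain regions and cell types also differed between libraries of one method. The serotonin neuron genes Slc6a4 and Tph2 had 36.1 and 49.4 CPM in TRIzol replicate 2 and at most 0.478 and 1.91 CPM in the other 5 libraries. The brainstem list, with 7 genes tested, did not pass (median log2 fold change 0.06, mean -1.07, adjusted p = 0.96 in camera). Its mean log2 deviation from each gene's mean was 2.37 in TRIzol replicate 2 and -1.33 to 0.75 in the other libraries. With that spread the test cannot exclude a shift. Pde10a, of striatal neurons, had 72.7 CPM in TRIzol replicate 3, 132 CPM in AllPrep replicate 3 and 136 to 418 CPM in the other 4 libraries. The striatal list's mean log2 deviation was 0.52, -0.44 and -1.59 in TRIzol replicates 1 to 3. It was 0.97, 1.04 and -0.50 in AllPrep replicates 1 to 3. Mbp, of myelin, had 1030 CPM in AllPrep replicate 3 and 1617 to 2191 CPM elsewhere.

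Single genes of lists that did not pass rose in AllPrep. Nrp2, a semaphorin receptor in the hippocampal list, went from 30.5 ± 10.2 to 82.3 ± 21.7 CPM (edgeR adjusted p = 0.039), while the list had a median of -0.08, a mean of 0.27 and adjusted p = 0.13. In the olfactory bulb list Synpr went from 92.4 ± 8.0 to 137 ± 3.24 CPM and Trh, thyrotropin-releasing hormone, which is also in the hypothalamic list, from 1.80 ± 0.524 to 10.3 ± 4.99 CPM. That list had adjusted p = 0.055 and passed in 5 alternatives. Slc1a3, an astrocyte glutamate transporter, went from 401 ± 23.3 to 536 ± 21.7 CPM (adjusted p = 0.037), and Cx3cr1 of microglia had 50.4 ± 1.86 against 40.9 ± 2.89 CPM without passing (adjusted p = 0.067). The astrocyte and microglial lists had adjusted p = 0.94 and adjusted p = 0.10.

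Choroid plexus genes were higher in AllPrep. Transcript length and GC content were argued against, since the median log2 fold change was 3.56 after both trends were removed and 13 of 15 genes still passed. Brain pieces that differ in the regions they hold might give such a shift, and 6 of 9 lists of regions and choroid plexus co-varied between libraries of one method above the 95th percentile of random lists. This does not decide it, because 19 of 29 other lists did so too (Fisher's exact test, one-sided, p = 0.64). The list means of the 9 varied more within methods, with a median pooled SD of 0.4527 against 0.1089 for the other lists, and 9 of 9 lay above the latter value. The comparison was not matched on abundance or list size, and some of the other lists varied as much (0.67 for ependymal and 0.65 for meningeal fibroblast genes). It goes with pieces that differ in region but cannot decide it. It also does not show whether such differences set AllPrep apart from TRIzol. Recovery set by the method would place AllPrep above TRIzol, as for 14 of 15 genes, but so would more choroid plexus in those pieces, so the explanations cannot be told apart and no biological one was tested.

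Lists of short housekeeping mRNAs had negative and that of very long brain genes positive medians in AllPrep relative to TRIzol. Of their members 3 of 184 and 5 of 33 passed, and no list passed camera with an estimated correlation (adjusted p = 0.67, 0.50 and 0.67 for the housekeeping lists and 0.32 for very long genes). For 184 ribosomal protein, oxidative phosphorylation and proteasome genes, the median of -0.30 lay at percentile 0.0 of random lists matched on length, whose median was -0.14, and at percentile 0.0 of lists matched on GC. Length may thus account for part of this shift, and whether it accounts for the whole is not decided. Length was that of the longest annotated transcript, and random lists do not keep the co-variation of these genes. Within methods the mean pairwise r was 0.66 for ribosomal proteins, 0.35 for oxidative phosphorylation and 0.38 for the proteasome. For very long brain genes the median of 0.29 lay at percentile 98.76 of lists matched on length, whose median was 0.14, and at percentile 100 of lists matched on GC. Whether length accounts for the latter stays open, since the percentile was 99.74 with the first matching rule, and no biological explanation was tested.

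Of 13 mitochondrial mRNAs, 5 had few counts (mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l), from 56 to 1247 per library, against 14984 to 1126830 for 7 others. Reads shared with nuclear copies are a candidate explanation: each of the 5 shared at least 97.59% of its 100-base words with an annotated nuclear pseudogene, and none of the 7 more than 60.75%. For mt-Atp8, with 32 to 67 counts, 0.0% was shared with an annotated copy. Only annotated transcripts were searched, so an unannotated copy could not be found and the question stays open for mt-Atp8. How reads with several matches were counted is not given in the sources used here, and no biological explanation was tested.

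The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 621 changed genes (412 higher, 209 lower, 139 at least 2-fold) and the highest other split 0 on each count, so 1 split of 10 reached each. For genes within 2-fold the real value was 13033 and the highest other 13300, and 10 splits reached it. A difference between the methods would lower this count, and the real value was the lowest of the 10, with 13111 to 13300 in the others. For gene lists the real value was 15 and the highest other 16, and 4 splits reached it. For the difference in coefficient of variation they were 0.0512 and 0.0786, and 3 splits reached it. The other splits mix the methods within a group, so they cannot decide on spread within a method.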
